A study of Drosophila melanogaster with 3 samples.

How the data were processed

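Gene expression was measured on 3 two-colour spotted cDNA slides, each hybridised with RNA of untreated Kc167 cells in both channels. Per the labels' protocols, the cells were kept as a dense culture at 22 °C, RNA was extracted with Trizol and labelled directly in each dye, and the labelled cDNAs competed for the array for 16 hours in 75 µL. Each labelling reaction took 80 µg of RNA for slides 1 and 2 and 40 µg for slide 3. Slides were scanned on a ScanArray instrument and quantified with QuantArray by its adaptive algorithm, with no background subtraction, per the labels' protocols.

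The deposited values are one log ratio per spot and slide, which the authors derived from normalized intensities, per the labels. The normalization method, the log base and the dye in the numerator are not given in the sources used here. That the values are on a log scale was read from the table, in which both signs are about equally frequent and the medians are 0.0008, 0.0003 and -0.0002 on slides 1 to 3. Neither centring by the authors nor its method is stated, and a normalization within each slide would remove any shift common to all spots. Test results are the same for any log base, whereas fold thresholds assume base 2. Intensities were not used here, so signal over background could not be weighed for any spot. Empty values made up 2.40% of spots on slide 1, 5.31% on slide 2 and 5.17% on slide 3, and the reason for them is not given in the sources used here.

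Gene names came from a platform annotation table, updated by gene identifier through the RefSeq gene table of assembly Release 6. It gave 1 symbol for 5666 spots (2377 genes), all of which matched, several symbols for 152 spots and none for 11078 spots, which are unnamed here. No coordinates are given, because no genome build goes with the files. The 16896 spots form 8448 pairs of neighbours. The 2 spots of a pair held the same symbol in all 2833 pairs that had 1 symbol on both, and neighbouring spots of different pairs shared a symbol in 0 cases.

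The fixed plan treated each spot as the table lists it. Spots with a value on all 3 slides (15412) were tested with limma 3.58.1 in R 4.3.3, by an intercept-only fit with empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No further centring or scaling was applied. The deposited unit differed from the plan, which foresaw rescaling a log ratio to base 2; with the base unstated, values were left as they were. Named genes followed a rule set before the data were examined. It takes the 10 largest means past the threshold per direction, and, where fewer pass, the genes with the largest smallest value of one sign on all slides until 8 are named. A gene is shown by its spot with the largest absolute mean, the 5 spots with the largest SD over slides are named, and each list is shown with the 2 members farthest from 0. Unnamed spots are limited to 2 per direction. Genes represented by at least 8 spots, and spot 16674, were named after their values were seen.

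Of 18 gene lists, also fixed beforehand and matched on exact symbols or, for ribosomal proteins, proteasome, histones and transposons, on symbol patterns, 8 had at least 3 measured genes and were tested with limma's fry and camera, adjusted over the lists; 4 had 1 or 2 measured genes and 6 had none. The pattern for proteasome subunits also matched Prosap, which is no proteasome gene and was left out. The lists covered ribosomal proteins, cytoskeleton, chaperones, proteasome, ecdysone response, plasmatocytes, muscle, neurons, immunity, fat body, histones and germ line. Those with no measured gene were translation factors, glycolysis, oxidative phosphorylation, cell cycle, transposons, and lamellocytes with crystal cells.

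Intervals for correlations came from 2000 bootstrap draws of the 32 blocks. The alternatives were median centring, equal scaling, quantile normalization, values on at least 2 slides, removal of extreme spots, gene means, other variance models, turned signs and leaving out each slide. Means of the 2 spots of a probe, removal of row means, other log bases and fry's mixed test without DnaJ-1, by probe means and by gene means were added after the data were seen. Data for 15412 spots were simulated as independent normal noise, with variances drawn from the prior that limma fitted to the real spots. The limma test recovered 74% of 50 spots shifted by 1.5-fold and 100% of 50 each shifted by 2-fold, 3-fold and 4-fold. There were 8 false calls among the 195 calls over all 4 sizes, and 0 calls where nothing was shifted. All 4 sizes were shifted together, which eases the adjusted threshold, so these shares do not carry over to data with few shifted spots. In the real data, spots 16583 and 16584 lay beyond 2-fold on all slides and had a limma adjusted p of 0.0666. Figures were drawn with matplotlib 3.10.9.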

Results

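Kc167 is an established Drosophila melanogaster cell line of embryonic origin. Total RNA from untreated Kc167 cells was labelled in both channels of 3 two-colour cDNA microarray slides, so that each slide compared the cells with themselves. A slide on which both channels hold the same RNA has an expected log ratio of 0 for every gene, and the series title names variability between slides as its subject. Slides 1 and 2 were made with 80 µg of RNA per labelling reaction and slide 3 with 40 µg. The design has 1 group of 3 slides and no treated or second cell population. The labels do not say that the slides came from separate cultures or extractions, so the p-values measure only the spread between these slides, which may be purely technical. Of the 16896 spots listed, 16491 had a log ratio on slide 1, 15998 on slide 2 and 16023 on slide 3, and 15412 had one on all 3 slides. The number of slides limits the precision of every value below. The log base of the deposited ratios and the dye in the numerator are not given in the sources used here, so signs carry no dye and folds assume base 2.

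The first comparison asked which genes left the expected log ratio of 0 in the same direction on all slides. Among genes with one of the 8 most consistent positive deviations were DnaJ-1, which encodes an Hsp40 co-chaperone, STUB1, which encodes an E3 ubiquitin ligase, and Obp59a, a member of the odorant-binding protein family. Plc21C, which encodes a phospholipase C, and Hsp60B, a member of the mitochondrial chaperonin family, led the named genes on the negative side. None of these genes, and no other spot, passed the test. In limma's moderated test of the mean against 0, 0 spots had a positive and 0 a negative mean at an adjusted p under 0.05, and the smallest adjusted p was 0.0666. At an unadjusted p under 0.05 there were 1280 spots, of which 700 were positive and 580 negative, against 770.6 given by chance. Without slide 3, 1 spot with a positive and 2 spots with a negative mean passed the same test.

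Plc21C had a log ratio of -0.60 ± 0.14 (SD, n = 3 slides), with values of -0.52, -0.76 and -0.53 on slides 1 to 3 and a limma adjusted p of 0.223. The second spot of the same probe averaged -0.11. Hsp60B stood at -0.45 ± 0.04 (SD, n = 3), again with a limma adjusted p of 0.223, and its second spot averaged -0.40. CG15576 averaged -0.79 ± 0.48 and ranged from -1.33 on slide 2 to -0.42 on slide 1, while its second spot averaged 0.09. CG13334 averaged -0.50 ± 0.30, CG10752 -0.37 ± 0.05 and CG3515 -0.34 ± 0.02, and their second spots averaged -0.19, -0.09 and 0.18. The last 2 negative genes were mio, which encodes a subunit of the GATOR2 complex, at -0.33 ± 0.02, and CG1909, at -0.33 ± 0.05, with second spots at -0.07 and -0.22. On the positive side, CG31778 averaged 0.51 ± 0.27, schuy 0.46 ± 0.22, CG31296 0.45 ± 0.20 and Obp59a 0.41 ± 0.23. CG4615 averaged 0.36 ± 0.10, CG34241 0.35 ± 0.08 and STUB1 0.32 ± 0.008, whereas their second spots averaged -0.12, -0.20 and 0.03. The chosen spot of DnaJ-1 averaged 0.38 ± 0.36 and fell below 0 on slide 3, at -0.03, whereas the other spot of that pair read 0.33, 0.40 and 0.38. Limma's adjusted p ran from 0.223 to 0.535 over these 16 genes. Among the 15 whose second spot was measured on all slides, 11 had the same sign on both spots. Each gene is shown by its spot farthest from 0, and the mean over all its spots was more than 1.5 times closer to 0 for 10 of the 16. These gene means were 0.19 for Obp59a, 0.17 for STUB1, 0.12 for CG4615, 0.10 for DnaJ-1, 0.01 for CG34241, -0.08 for CG3515, -0.20 for mio, -0.23 for CG10752, -0.35 for CG15576 and -0.36 for Plc21C.

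**Figure D1:**
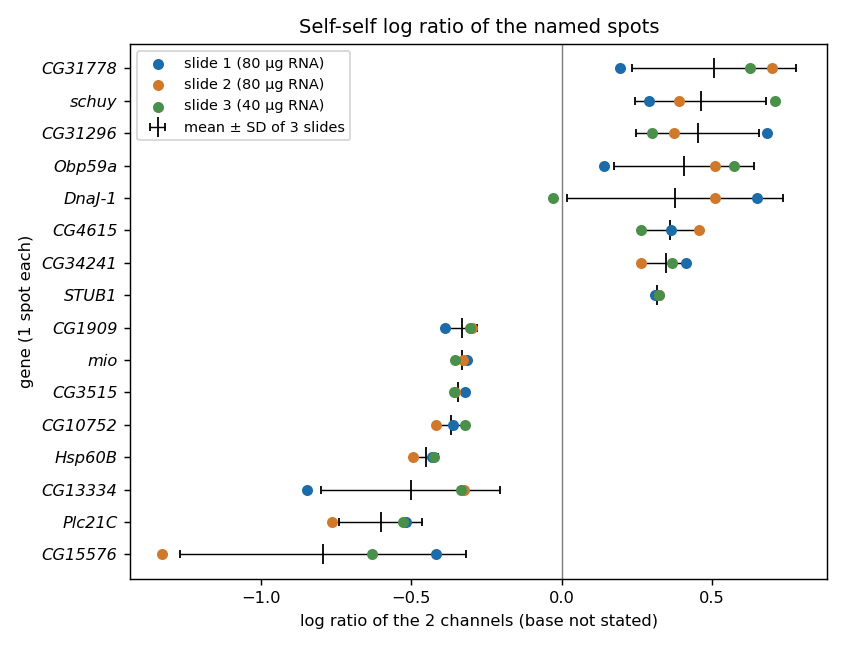
Log ratio of 1 spot for each of the 16 named genes (horizontal axis, log units of unstated base). Coloured points are the 3 slides, and black marks with bars are the mean ± SD of the 3. Apart from DnaJ-1, whose slide 3 value was -0.03, each gene had all 3 points on the same side of 0.

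The spots that stayed farthest from 0 on all slides had no gene name in the annotation used here. The 2 neighbouring spots numbered 16583 and 16584, which form 1 probe, averaged -1.43 ± 0.30 and -1.51 ± 0.36 (SD, n = 3 slides), with a limma adjusted p of 0.0666 for each. This probe passed the test under quantile normalization (adjusted p = 0.0134 for each spot), as the mean of its spots (0.0226) and without slide 3 (0.0033 and 0.0031). Spot 16303 averaged 0.65 ± 0.04 and spot 14774 averaged 0.65 ± 0.06, and their second spots averaged 0.39 and 0.23. These 4 spots, from 3 probes, were the only ones of the 15412 beyond 1.5-fold (a log ratio of 0.585 at base 2) in one direction on all slides. When the spots of 2 slides were shuffled 10000 times, chance gave a mean of 0.0092 such spots and never more than 1 (one-sided permutation p = 0.0001, the smallest these shuffles can give). Shuffling pairs of spots together gave the same p of 0.0001. The count of 4 became 1 by means over the 2 spots of a probe, 2 with row means removed and 12 with values on at least 2 slides. With 2 slides in place of 3 the count was 28 without slide 1, 9 without slide 2 and 12 without slide 3. Beyond 2-fold on all slides there were 2 spots, those of the probe at 16583 and 16584.

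The 5 spots that differed most between slides did so through 1 slide each. Hsp60C, a second member of the mitochondrial chaperonin family, read -2.42 on slide 1 against 0.22 on slide 2 and 0.26 on slide 3 (SD 1.54, n = 3). CG7409 read -2.05 on slide 2 against -0.32 and 0.37 on slides 1 and 3. CG8065 read -2.08 on slide 1 against 0.20 and -0.09 on slides 2 and 3. The second spots of these probes averaged -0.08 for Hsp60C, 0.07 for CG7409 and -0.07 for CG8065. The other members of the set of 5 had no gene name: spot 5704 read 2.56 and spot 10390 read -2.22, both on slide 2.

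Gene groups fixed in advance were examined next. No member passed the test in any of the 12 lists that had measured genes. This follows from the 0 spots that passed over all spots and adds nothing to that result. Tests of the lists themselves are given below. The 5 measured ribosomal protein genes had a median spot log ratio of 0.07, with medians of 0.04, 0.09 and 0.15 on slides 1 to 3. RpS15Ab averaged 0.34 ± 0.14 (SD, n = 3 slides). RpL32, a gene often used as an expression reference, supplied 18 of the 26 spots, of which the one farthest from 0 averaged -0.36 ± 0.49 while the mean over all 18 was 0.04. The 6 heat shock and chaperone genes had a median of -0.02 over 32 spots, with CCT1, a subunit of the cytosolic chaperonin, at -0.28 ± 0.31 beside DnaJ-1. For the 5 actin, tubulin and cytoskeleton genes the median was 0.02, with alphaTub84D at -0.21 ± 0.22 and betaTub85D at 0.13 ± 0.14. The 14 proteasome genes had a median of -0.0093, with Prosbeta4R2 at -0.26 ± 0.19 and Prosalpha4T1 at 0.13 ± 0.14. Tubulin, proteasome and ribosomal protein genes have close paralogs whose cDNA can bind the same spot, so their values are uncertain as to the gene.

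The 8 plasmatocyte (macrophage-like blood cell) markers had a median spot mean of 0.03, with medians of 0.02, -0.06 and -0.03 on slides 1 to 3. The members farthest from 0 were Pvr, which encodes a receptor tyrosine kinase, at -0.22 ± 0.18, and vkg, a collagen IV chain, at -0.20 ± 0.08. The 6 ecdysone response genes had a median of 0.01, with the nuclear receptor gene ftz-f1 at 0.34 ± 0.38 and ImpE3 at -0.09 ± 0.40. The 5 muscle genes had a median of -0.02, with Tm2, a tropomyosin, at 0.24 ± 0.17 and TpnC73F, a troponin C, at 0.17 ± 0.06. The 4 neuronal genes had a median of 0.09, with fne, an ELAV-family RNA-binding protein gene, at 0.26 ± 0.46 and the synaptobrevin gene nSyb at 0.11 ± 0.06. A further 4 lists had only 1 or 2 measured genes. Tep4 and Dif of the immunity list averaged -0.26 ± 0.27 and -0.14 ± 0.18, apolpp and Fbp2 of the fat body list -0.21 ± 0.37 and 0.12 ± 0.43, the linker histone gene BigH1 0.08 ± 0.23 and the translational repressor gene pum, from the germ line list, 0.08 ± 0.11. Among the 21 list members named for the 12 lists, DnaJ-1 aside, the mean over all spots of the gene was more than 1.5 times closer to 0, or on its other side, for 12. Apart from RpL32 these gene means were 0.21 for RpS15Ab, -0.15 for Prosbeta4R2, 0.08 for Prosalpha4T1, -0.12 for vkg, 0.08 for ftz-f1, -0.0031 for ImpE3, 0.04 for Tm2, 0.05 for TpnC73F, 0.09 for fne, -0.07 for apolpp and 0.05 for Fbp2. The other 6 lists had no measured gene under the symbols and patterns fixed for them.

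Taken by spots, 0 of the 8 lists tested passed limma's fry test for a move to one side of 0, in which the smallest adjusted p was 0.187. Taken by gene means, 2 passed. The neuronal genes averaged 0.05, 0.06 and 0.06 on slides 1 to 3 (fry adjusted p = 0.0118), and the plasmatocyte markers 0.0041, -0.0050 and -0.0121 (fry adjusted p = 0.0288, called downward although their median was 0.04). By means over the 2 spots of a probe 0 lists passed, with a fry adjusted p of 0.0896 for each of these lists. The counts past the test adjusted over the list alone were 1 spot, the DnaJ-1 spot next to the one chosen above, in the heat shock list (adjusted p = 0.0435) and 0 in the others. With members allowed to move either way, fry's mixed test by spots passed for the heat shock list (adjusted p = 0.00094) and the plasmatocyte list (adjusted p = 0.0221). DnaJ-1 supplied 16 of the 32 heat shock spots, and without it that list no longer passed (adjusted p = 0.589), nor did it by probe means (0.127) or by gene means (0.492). The plasmatocyte call was lost by probe means (adjusted p = 0.106) and by gene means (0.124). Camera with its preset correlation placed the ribosomal protein spots above the rest (adjusted p = 0.0288), and this call was lost with an estimated correlation (adjusted p = 0.987) and without slide 2 or slide 3, by gene means, by probe means and with row means removed, when 0 lists passed.

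At least 8 measured spots represented each of 27 genes, which gives a value of the gene from several places on the slide. The mean over the 16 DnaJ-1 spots was 0.02, 0.13 and 0.15 on slides 1 to 3, or 0.10 ± 0.07 (SD, n = 3 slides), and 11 of the 16 spots had a positive mean. SKIP had the mean farthest from 0, at -0.11 ± 0.06 over 8 spots, of which 0 had a positive mean. CG9016, with 38 spots, averaged 0.02 ± 0.05, and CG12902, with 24 spots, averaged 0.02 ± 0.06. On slide 1 the SD over the spots of 1 gene ran from 0.11 for mil to 0.41 for CG18449. It was 0.30, 0.27 and 0.27 for DnaJ-1 and 0.33, 0.20 and 0.13 for RpL32 on slides 1 to 3.

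The second comparison was of the error of single slides. The log ratios had an SD of 0.218 on slide 1, 0.203 on slide 2 and 0.193 on slide 3, or 0.205 ± 0.013 (SD, n = 3 slides). The median absolute deviation, scaled to equal the SD of normally distributed values, differed less, with 0.165 ± 0.001 over the same slides. Whether the authors scaled the slides to each other is not stated, so this closeness may come from the normalization. On slide 1, 1.88% of spots (Wilson 95% interval 1.68 to 2.11) lay beyond 1.5-fold, against 1.54% (1.36 to 1.75) on slide 2 and 1.17% (1.01 to 1.35) on slide 3. Beyond 2-fold were 0.415% of the spots on slide 1 (0.325 to 0.530), 0.117% on slide 2 (0.0739 to 0.185) and 0.0779% on slide 3 (0.0445 to 0.136). These intervals cover the counting of spots only. Of the 64 spots beyond 2-fold on slide 1, 61 were negative, against 8 of 18 on slide 2 and 8 of 12 on slide 3. Beyond 1.5-fold, slide 1 had 74 positive and 216 negative spots. Slides 2 and 3 leaned the other way there, with 191 positive and 47 negative spots on slide 2 and 123 and 57 on slide 3.

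The third comparison set the error between slides against that within a slide. The table listed the 2 spots of each probe next to each other, and all 2833 pairs with 1 gene symbol carried the same symbol on both spots. The SD of a spot, estimated from the difference between the 2 spots of a probe on the same slide, was 0.188 on slide 1, 0.158 on slide 2 and 0.162 on slide 3. Estimated from the difference between the same spot on 2 slides, it was 0.205 for slides 1 and 2, 0.196 for slides 1 and 3 and 0.174 for slides 2 and 3. The sets of spots differed: all pairs measured on the slide (8149, 7809 and 7880) within slides, and the 15412 spots measured on all slides between them. Duplicate spots correlated across probes with an r of 0.29, 0.39 and 0.33 on slides 1 to 3, while neighbouring spots of different probes correlated with an r of 0.12, 0.22 and 0.14. The median SD of a spot over the 3 slides was 0.130, with a 5th to 95th percentile range of 0.034 to 0.360. On average 12.3% of a slide's variance was shared with another slide, and that share was 23.2% without slide 1 and 5.33% without slide 3.

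Slides 2 and 3 deviated from 0 together more than the other pairs did. Across the 15412 spots, which are not independent replicates, Pearson's r was 0.23 for slides 2 and 3 (Spearman's rho 0.22), 0.10 for slides 1 and 3 (rho 0.10) and 0.05 for slides 1 and 2 (rho 0.03). Averaged over the 2 spots of a probe, r was 0.32 (95% bootstrap interval over array blocks 0.29 to 0.35), 0.14 (0.12 to 0.18) and 0.08 (0.043 to 0.116) for the same pairs. All 3 slides held the same sign for 30.5% of spots, against 25% given by chance.

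**Figure D2:**
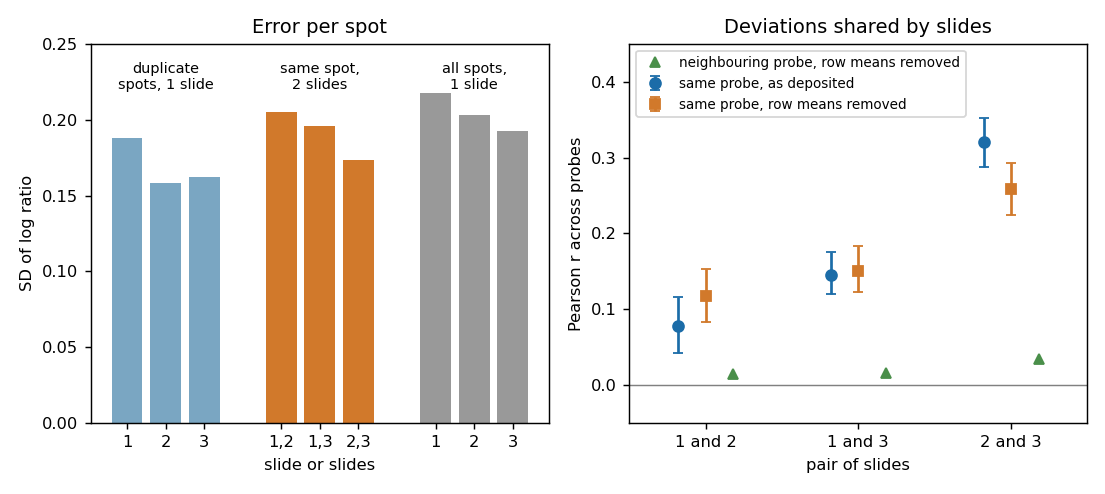
Left, SD of the log ratio of a spot from duplicate spots on 1 slide, from the same spot on 2 slides, and over all spots of a slide, in log units. Duplicates were all pairs measured on that slide, and the other bars used the 15412 spots measured on all slides. Right, Pearson's r across probes for each pair of slides with 95% bootstrap intervals over the 32 blocks, for the same probe before and after row means were removed and for the neighbouring probe; r for slides 2 and 3 was 0.32 and 0.26 for the same probe.

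Position on the array was examined as a batch within slides. Spots 24 places apart in the table correlated on each slide, with an r of 0.13 to 0.18, against 0.0061 to 0.11 at 20 places, and the table divides into 32 blocks of 528 spots, or 22 rows of 24. This layout was inferred from the values. Row means over the 32 blocks accounted for 1.78% of the variance on slide 1, 13.2% on slide 2 and 4.35% on slide 3, while block means accounted for 0.50% on slide 1 and less on the others. On slide 2 the first row averaged 0.19 and the tenth -0.11, and on slide 3 the same rows averaged 0.10 and -0.05. With the row means removed, r over probe means was 0.26 for slides 2 and 3 (0.22 to 0.29), 0.15 for slides 1 and 3 (0.12 to 0.18) and 0.12 for slides 1 and 2 (0.083 to 0.153). Under that removal 0 spots passed limma's test in either direction.

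**Figure D3:**
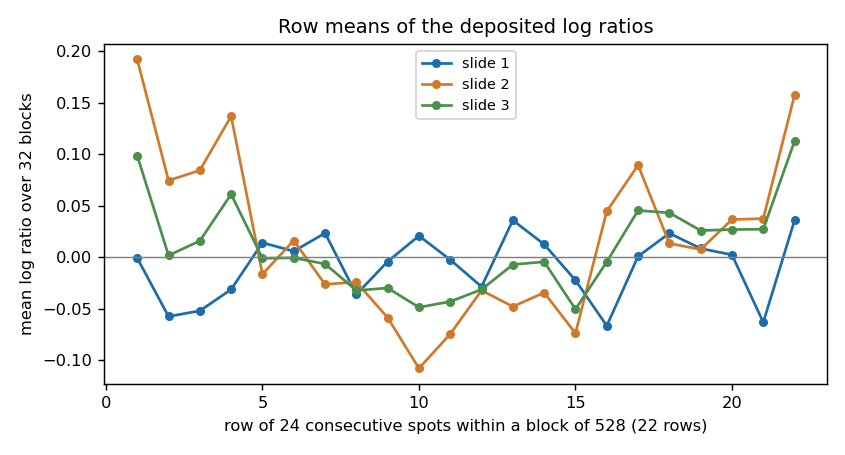
Mean log ratio of each of the 22 inferred rows of 24 spots, taken over the 32 blocks (vertical axis, log units), for the 3 slides. Slides 2 and 3 were both highest in rows 1 and 22, where slide 2 averaged 0.19 and 0.16 and slide 3 averaged 0.10 and 0.11.

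The last comparison concerned the RNA amount, for which there was 1 slide at 40 µg and therefore no replicate check. The slide made with 40 µg differed from the mean of the 80 µg slides with an SD of 0.178 per spot, scaled so that slides of equal error give equal values. The 80 µg slides differed from each other with an SD of 0.205, which gave a ratio of 0.868. The same ratio was 1.20 with slide 1 and 0.960 with slide 2 set apart in place of slide 3. The median difference of the 40 µg slide from the other slides was 0.0016. Each slide's own median was already near 0, at -0.0007, -0.0023 and -0.0021 on slides 1 to 3. If the authors centred each slide, this difference was near 0 whatever the RNA amount did.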

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

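The means over the 2 spots of a probe, the removal of row means, the other log bases and the mixed list test without DnaJ-1, by probe means and by gene means were chosen after the data were seen. The count of 0 spots past limma's test held under centring, scaling, gene means, values on at least 2 slides, robust or no moderation and row removal. It did not under quantile normalization (2 negative spots, 16583 and 16584), probe means (1 negative probe, the same one) or without slide 3 (2 negative, again those spots, and 1 positive, spot 16674); leaving out 1 slide gave 0 to 2 negative and 0 to 1 positive. With the sign of slide 1, 2 or 3 turned, the count past limma's test was also 0, and that at an unadjusted p under 0.05 was 811, 498 and 395. Turning a sign cancels deviations shared by the slides, so that 0 does not bear on how stable the result is. The 4 spots beyond 1.5-fold on all slides became 12 with values on at least 2 slides, 1 for probe means, 2 with row means removed, 2 at 2-fold and 9 to 28 with 1 slide left out, where fewer slides have to agree. Read as natural logs they became 23, and as logs to base 10 they became 345. The shares beyond 1.5-fold on slides 1 to 3 were then 5.50%, 4.76% and 4.21%, or 30.4%, 30.7% and 30.1%, and for probe means 0.924%, 0.576% and 0.428%. The SD of the slides was 0.172, 0.163 and 0.153 for probe means, and 0.190 on slide 2 with row means removed. The median SD over slides was 0.103 for probe means. With 1 slide left out it was 0.0976 to 0.112, and the shared variance was 5.33% to 23.2%. An SD over 2 values has a lower median than 1 over 3 values at the same error, so that drop shows no smaller spread. In all, 2 lists passed fry on gene means, with neuronal genes at adjusted p = 0.0118 and plasmatocyte markers at 0.0288, the latter called downward at a mean of -0.0043 and a median of 0.04; the cause was not tested. The 1 camera call fell to 0 on gene means, probe means and with row means removed, and was 0 to 1 with 1 slide left out. Of the 41 named genes and spots, the only ones recomputed under these settings, 4 listed genes, none of them past the test, changed sign with 1 slide left out: apolpp (-0.315 to 0.0067), BigH1 (-0.0103 to 0.214), Fbp2 (-0.130 to 0.272) and ImpE3 (-0.319 to 0.0492). With 1 slide left out, other genes kept their sign but varied in size, such as RpL32 (-0.509 to -0.0706), ftz-f1 (0.163 to 0.542) and DnaJ-1 (0.241 to 0.582). RpL32 changed sign as a gene mean (0.0429), and the mean over all spots of a gene was more than 1.5 times closer to 0 for 10 of the 16 named genes. No spot lay beyond 8-fold, so that filter removed nothing, and the list tests and the RNA comparison were not run on spots measured on only 2 slides. The log ratio itself pairs the 2 channels of a slide. No pairing of samples between groups was possible because there is 1 group. With no intensities used here, what low signal limits stays unknown.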

Other observations

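Of the gene families outside the fixed lists, 3 were tested, which the fixed plan did not include. The odorant-binding proteins, small carrier proteins of sensory organs, had 20 measured genes on 51 spots with a median log ratio of 0.02. Of the 51 spots, 31 had the same sign, a count for which no chance level is given. This family did not pass the test (fry adjusted p = 0.573 over 4 families), although Obp59a was among the genes with the most consistent positive values. The UDP-glycosyltransferases (Ugt) had 7 genes with a median of 0.03 and the Rab GTPases 5 with a median of 0.01, neither past the test at adjusted p = 0.715. The last family in that adjustment, the proteasome beta subunits, belongs to the fixed proteasome list.

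Tests of the RNA amount, of the probe itself and of shuffles within blocks were chosen after the result was seen. Turned signs were a planned setting whose prediction was written after the result. For the random placements of slide 1 tail spots no prediction was written. The other tests had their prediction written first. For the slide 1 tail, however, the verdict on single spots and on lasting deviation was set after the values were seen. It went by whether intervals, those over blocks included, excluded the predicted value. Slides 2 and 3 deviated together with an r of 0.32 over probe means. A shared RNA amount cannot be why slides 2 and 3 deviated together, since they were made with 80 and 40 µg. The slides that shared 80 µg had the lowest r, 0.078. With 1 such pair, an effect of the amount cannot be told apart from a trait of slide 1. A gradient over rows common to slides 2 and 3 is not the whole cause, because r was still 0.258 with row means removed, although the neighbouring probe's r fell from 0.12 to 0.034. A deviation that belongs to the probe is a candidate explanation. With row means removed, r for the same probe exceeded r for the neighbouring probe by 0.224 (95% bootstrap interval 0.19 to 0.26). A dye preference of the probe's sequence would act so. This excess cannot tell it from other fixed traits of the spot, such as its signal, since intensities were not used. The same excess was 0.10 for slides 1 and 2 and 0.13 for slides 1 and 3. Why slide 1 shares less, and whether rows differ by position or by the clones printed in them, stays open. No biological explanation was tested. Both channels of each slide held RNA of the same untreated cells, so the design sets no difference in expression between them.

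On slide 1, 69 spots lay below -1 against 9 on slide 2 and 9 on slide 3. A lasting deviation of those spots as a set, for which medians under -0.3 were predicted, is argued against by their medians on the other slides, -0.035 on slide 2 (95% bootstrap interval over blocks -0.10 to 0.11) and -0.029 on slide 3 (-0.08 to 0.08). The probe at spots 16583 and 16584 is an exception within this tail. Its spots read -1.68 and -1.76 on slide 1, -1.51 and -1.66 on slide 2, and -1.10 and -1.10 on slide 3. For faults of single spots, under 10% of the tail spots were predicted to have a second spot below -1 too, and over 30% if these were not the cause; the share was 26.5%, with a 95% bootstrap interval over blocks of 4.76 to 40, which leaves open how much of the tail such faults make up. They are argued against only for the 18 spots, or 9 pairs, with both spots below -1, since 10000 shuffles of the values within blocks gave at most 10 such spots. Areas of the slide may account for part: 1 block of 528 held 18 of the 69, where 10000 random placements of single spots gave at most 11. That maximum may be too low, because tail spots came partly in pairs and pairs were not placed together. The 32 spots outside the 3 fullest blocks leave open how much of the tail such areas cover.

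The 1280 spots at an unadjusted p under 0.05 were 1.66 times the number chance gives. Rows are argued against as the cause, since the count was 1259 with row means removed. Of the 4 arrangements of the slides' signs, 1, the real one, gave as many, and the highest of the others was 811; 4 arrangements are too few for a share under 0.05.

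On slide 3, 253 of the 873 empty spots lay in 1 block, where the next fullest block had 40 and the median block 20. The scaled median absolute deviations of the slides, 0.164, 0.166 and 0.165, lay much closer together than their SDs. The normalization method is not given in the sources used here, and a scaling of the slides by the authors could have produced this.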
